A study of Mus musculus with 13 samples.

How the data were processed

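Olfactory bulb RNA of C57BL/6 mice was measured by RNA sequencing in 13 samples, with 1 library per sample. Per the labels, RNA was extracted with an RNeasy mini kit and libraries were made with a TruSeq Stranded Total RNA kit. The labels place the libraries in a 1st set, with 4 control samples and 3 samples of mice given the lower dose of fine particulate matter (PM2.5, airborne particles of small diameter), and a 2nd set, with 3 control samples and 3 samples of mice given the higher dose. The doses are labelled 3 and 10 mg/kg with "/3 day". Whether this means 1 dose every 3 days or a dose over 3 days, the route of exposure and the meaning of 1st and 2nd are not given in the sources used here. Mice were aged 7 to 8 weeks per the labels. The labels number the samples within each group and say nothing more on how the replicates were drawn, so p-values measure the spread between these samples.

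The deposited table holds 34745 genes with Ensembl identifiers, symbols and mouse coordinates. The submitters' processing notes name HISAT2 as a tool and mm10 as the genome build, with no version. For each library the authors deposited a raw count per gene and an FPKM value. The counting program, the annotation release and the strand setting of the counting are not given in the sources used here. For genes of high count in every library, the count was divided by the FPKM and by the library's total count. The quotient was constant across libraries for each gene, with a largest relative deviation of 2.76e-06. It was taken to stand for gene length, which was not compared with an annotation. The FPKM thus carries no scaling between libraries beyond depth. The gene coordinates were compared with GENCODE M21, an annotation of the same build (GRCm38). Of 34267 genes matched by identifier, 27699 had identical coordinates, and the gene type and strand of named genes were taken from that annotation. Because strand use in the counting is unknown, reads of a gene and of a partner on the opposite strand could have been counted together. Genes named in the text that overlap an annotated gene on the opposite strand are Xist (with Tsix), Gm42418, Malat1, Icam1, Gfap, Cxcl10, Plin4, Ch25h, Lama3, Pycard, Gbp2, Ciita, Slc2a1, Nr1d1, Hif3a, Hspa1a, Il1b, Rab7, Tomm40l, Gpr17, Bcas1, F13a1, Matn2, Adcy3, Ebf2, Abcc4, Gnal and Ddc.

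Total counts ran from 13 to 27.0 M per library. Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, robust quasi-likelihood F test), in 1 fit of 4 groups over the 13 libraries with 9 residual degrees of freedom. The filter kept 17467 genes. Contrasts were the low dose against the controls of the 1st set, the high dose against the controls of the 2nd set, the difference and the mean of these responses, and the controls of the 2nd set against those of the 1st. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Standard errors of log2 fold changes (SE) are the fold change divided by the square root of F, and are approximate. CPM values are counts scaled by the TMM-adjusted total of the library, and values in the text are means ± SD over the libraries of a group. Where every control library held 0 counts, a fold is given as a lower bound against 3 counts over the control group.

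Before the data were examined, 51 gene lists for cell types, stress responses and signalling pathways of this tissue were fixed. They were tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list with all other genes, adjusted over the 51 lists. Camera with an estimated correlation and fry, a test of whether the genes of a list move one way on balance, were run beside it. Some lists share members, such as Lcn2 and Cxcl10, so their calls are not independent. Of the lymphocyte list only 1 member (Ighm) was measured, so its result stands for that gene (log2 fold change -0.09 at the low dose and 0.12 at the high dose, neither called). Genes named in the text follow a rule fixed at the same time. For each dose these are the 8 largest rises and the 8 largest falls among genes that passed, with a mean of at least 1 CPM, all exposed libraries on one side of all controls of the set and a symbol that is not a bare gene-model name. If no gene passed in a direction, the 4 with the smallest p are given as values that did not pass. The 2 members with the smallest p of each called list and of 7 lists of interest are also named, as are up to 4 rises and 4 falls of the difference and mean contrasts. Other genes were chosen after their values were seen, as were the markers Hbb-bs and Cyp2a5 given for single libraries. Not every gene that the rule selects is given in the text.

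Replicates were compared before averaging. No pair of libraries in a group agreed within sampling noise: the lowest chi-square per gene was 6.09, and log CPM correlations ran from 0.970 to 0.986. Alternatives set before the data were examined were DESeq2 size factors and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in every library, the replicate number as a block, each library left out in turn, the DESeq2 1.42.0 Wald test, limma-voom, a separate fit within each set, controls of both sets pooled, limma trend on log2(FPKM + 1) with an FPKM of at least 1 in at least 3 libraries, and a fold threshold of 1.5. Alternatives added later were the leading residual component as a covariate, every library thinned to the lowest total, removal of Gm26917, Gm42418 and mitochondrial genes, removal of X and Y genes, and removal of the deepest control and exposed library of the 2nd set. The estimated correlation with each library left out and the list tests of the mean response were also added later. The steps were tested on simulated counts with 200 changed genes per contrast. Of genes changed 4-fold, edgeR recovered 57 of 66 in the low-dose contrast and 62 of 66 in the high-dose contrast, and of genes changed 1.5-fold 17 of 67 and 23 of 67, with 8 and 4 false calls. Of all calls, 8 of 131 and 4 of 126 were false with edgeR. With the DESeq2 Wald test 26 of 171 and 21 of 153 were false, a larger share. These figures apply to the simulated spread of the 17265 genes in that fit.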

Results

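Olfactory bulb RNA of 13 samples was compared at 2 doses of PM2.5 with controls of the same set. The 1st set held 4 control libraries with 13 to 14.1 M counts and 3 libraries at 3 mg/kg with 14.3 to 14.7 M. The 2nd set held 3 control libraries with 15.4 to 27.0 M counts and 3 libraries at 10 mg/kg with 20.2 to 25.5 M. Each library held a count for 20406 to 21316 genes. Transcripts of Gm26917 and Gm42418, which carry ribosomal RNA sequence, made up 2.70 to 3.62% of the counts, and mitochondrial genes 2.11 to 2.90%. The low dose was given only in the 1st set and the high dose only in the 2nd, so each dose was compared with the controls of its own set. The series is labelled as male mice. Xist, a transcript of the inactive X chromosome, stood at 2245 to 2712 CPM in all 7 libraries of the 1st set and at 0.0992 to 0.555 CPM in all 6 libraries of the 2nd set. The sum of 4 Y-linked genes stood at 0 to 0.210 CPM in the 1st set and at 177 to 230 CPM in the 2nd. Expression of sex-linked genes thus parted the sets, and dose, set and the sex of the libraries cannot be separated beyond the comparison with each set's own controls. The leading principal component held 41.2% of the variance and separated the sets.

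At the high dose, some genes of the NF-kB, complement and reactive astrocyte lists rose in the olfactory bulb, and 3 immediate early genes fell. Icam1, which encodes an adhesion molecule of activated endothelium and leukocytes (ENSMUSG00000037405, mm10 chromosome 9, 21015960 to 21028797), rose from 1.44 ± 0.133 CPM in control libraries (SD, n = 3) to 9.38 ± 0.925 CPM (SD, n = 3), a log2 fold change of 2.71 (SE 0.21, adjusted p = 3.69e-05). Ccl12, a chemokine that attracts monocytes (ENSMUSG00000035352, mm10 chromosome 11, 82101845 to 82103400), rose by a log2 fold change of 5.33 (SE 0.54, adjusted p = 0.000763), from 0.20 ± 0.175 to 8.66 ± 5.0 CPM. Gfap, the intermediate filament of astrocytes (ENSMUSG00000020932, mm10 chromosome 11, 102887336 to 102900912), rose from 211 ± 33.4 to 540 ± 98.6 CPM (log2 fold change 1.36, SE 0.16, adjusted p = 0.00171). Npas4, a transcription factor gene induced by neuronal activity (ENSMUSG00000045903, mm10 chromosome 19, 4984355 to 4989971), fell from 68.5 ± 16.1 to 18.9 ± 5.63 CPM (log2 fold change -1.85, SE 0.21, adjusted p = 0.00171). In all, 112 of 17467 genes passed, 91 higher and 21 lower.

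Besides Ccl12, the largest rises that met the naming rule were in Msr1, a scavenger receptor of macrophages (log2 fold change 5.37), Lrg1 (3.81), Tmem252 (3.73), Plin4, a lipid droplet protein (3.53), Cxcl10, a chemokine induced by interferon (3.15), C5ar1, the receptor of complement C5a (3.13), and Ch25h, which makes 25-hydroxycholesterol (3.05), with adjusted p from 0.00242 to 0.0173. The base levels of these genes were low, with control means from 0.0863 to 0.765 CPM. Besides Npas4, the largest falls were in Cyp2e1 (-2.16), Btg2 (-1.18), Ier2 (-1.16), Rhcg, an ammonium transporter (-1.11), Lama3, a laminin chain (-1.11), Kcnh8, a potassium channel (-0.93), and Slc40a1, the iron exporter ferroportin (-0.89), with adjusted p from 0.00845 to 0.0375. Sele, which encodes E-selectin of activated endothelium, had no count in any control library of either set and stood at 1.25 ± 0.101 CPM at the high dose, at least 23.9-fold higher than the control floor.

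**Figure D1:**
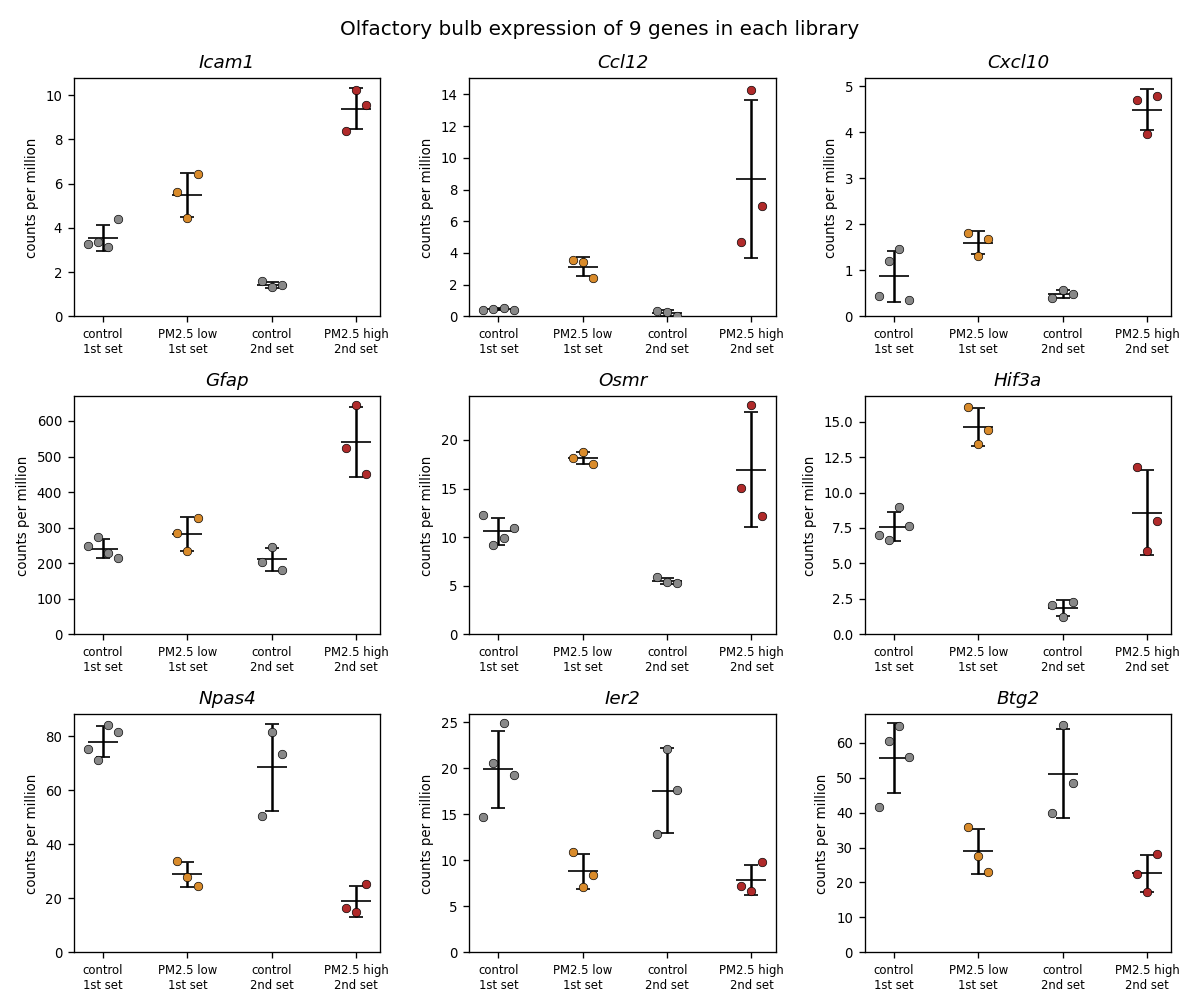
CPM of 9 named genes in each of the 13 libraries, by group, with points for libraries, wide bars for the group mean and error bars of 1 SD; each panel has its own axis from 0. Icam1 stood at 1.44 ± 0.133 CPM in the controls of the 2nd set and at 9.38 ± 0.925 CPM at the high dose, and Npas4 at 78.1 ± 5.85 and 28.9 ± 4.67 CPM in the controls and exposed libraries of the 1st set.

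Gene lists fixed in advance were then tested at the high dose. Of 13 measured genes of NF-kB feedback and acute phase, 6 rose, among them Icam1 and Sele, and none fell. Adjusted over the list alone, 11 rose. Their median log2 fold change was 1.14 (camera adjusted p = 5.83e-36, and adjusted p = 0.000308 with an estimated correlation). Of 13 complement genes 6 rose and none fell, and 11 rose when adjusted over the list alone. C3ar1, the receptor of C3a, rose by a log2 fold change of 1.3 (SE 0.25, adjusted p = 0.0283). The list's median was 1.04 (camera adjusted p = 1.15e-26, and adjusted p = 0.00513 with an estimated correlation). Of 18 reactive astrocyte genes 5 rose, among them Gfap and Osmr, the oncostatin M receptor (log2 fold change 1.62, SE 0.21, adjusted p = 0.00242). Adjusted over the list alone, 13 rose. Their median was 1.14 (camera adjusted p = 5.57e-30, and adjusted p = 0.00339 with an estimated correlation). Of 22 listed cytokines and chemokines 11 were measured. Il6 and Tnf, named after their values were seen, were too low in count to be tested. Of the 11 measured genes 2 rose (Ccl12 and Cxcl10) and 1 fell (Cxcl12, named after its value was seen, log2 fold change -0.66). Of these genes 5 rose and 1 fell when adjusted over the list alone. The list was called higher (median 0.38, camera adjusted p = 1.26e-07, and adjusted p = 0.0276 with an estimated correlation).

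The calls of 4 more lists that were higher at the high dose held with an estimated correlation. Of 6 neutrophil genes 1 rose (S100a9, log2 fold change 2.59, SE 0.40, adjusted p = 0.00845), and 4 when adjusted over the list alone (camera adjusted p = 2.58e-11, and adjusted p = 0.00181 with an estimated correlation). Of 13 inflammasome and innate sensing genes 1 rose, Pycard, an adaptor of the inflammasome (1.05, SE 0.20, adjusted p = 0.0283), and 8 when adjusted over the list alone (2.04e-10 by camera, adjusted p = 0.0163 with an estimated correlation). Of 16 glucocorticoid-responsive genes 3 rose, among them Hif3a (2.24, SE 0.27, adjusted p = 0.00192) and Plin4, and 6 when adjusted over the list alone (3.44e-13 by camera, adjusted p = 0.0163 with an estimated correlation). Of 12 antigen presentation genes 1 rose, Ciita, the MHC class II transactivator, which had no count in the controls of the 2nd set and was at least 7.00-fold higher than their floor. Of that list, 6 genes rose when adjusted over the list alone (1.99e-10 by camera, adjusted p = 0.0425 with an estimated correlation). The medians of these 4 lists were 2.32, 0.95, 0.46 and 0.71, and setting Sele and Ciita to their bounds left the list medians as given. With 1 library left out, the calls with an estimated correlation for NF-kB, complement, reactive astrocyte and neutrophil genes were kept in each case. Those of cytokines, inflammasome genes and glucocorticoid-responsive genes were lost without control replicate 1, control replicate 2 or exposed replicate 3 of the 2nd set. Cytokines had an adjusted p of 0.0721 and 0.107 without control replicates 1 and 2. Inflammasome genes had 0.0693 and 0.0756 without these and 0.0535 without exposed replicate 3, and the adjusted values of the glucocorticoid list were the same. That of antigen presentation was lost without any 1 of control replicates 1, 2, 3 and 4 or exposed replicate 3 of the 1st set, or control replicates 1, 2 and 3 or exposed replicates 2 and 3 of the 2nd set (highest adjusted p 0.141).

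The calls of other lists were lost with an estimated correlation, whose adjusted p is given. Of these, fry also called interferon-stimulated genes (adjusted p = 0.0245), perivascular macrophages (0.0260), astrocyte markers (0.0333), oligodendrocyte precursors (0.0333), interneurons and granule cells (0.0386) and cholesterol synthesis (0.0386). Of 23 immediate early genes 3 fell (Npas4, Btg2 and Ier2) and 1 rose (Ier3), and 13 fell and 3 rose when adjusted over the list alone. The median was -0.93 (camera adjusted p = 4.12e-14, and adjusted p = 0.146 with an estimated correlation). Interferon-stimulated genes were higher (median 0.76, adjusted p = 0.0557 with an estimated correlation), with Gbp2, an interferon-induced GTPase, at 1.69 (SE 0.21, adjusted p = 0.00242) and Ifitm3 at 1.09 (SE 0.21, adjusted p = 0.0312) as the 2 genes of 24 that rose. Perivascular and peripheral macrophage genes were higher (median 1.07, adjusted p = 0.0577 with an estimated correlation), with Cd163 rising by 1.72 (SE 0.37, adjusted p = 0.0488). Astrocyte markers were also called higher (median 0.18, adjusted p = 0.113 with an estimated correlation). So were red blood cell genes (median 0.90, adjusted p = 0.219 with an estimated correlation), endothelial genes (0.25, adjusted p = 0.250), activated microglia genes (0.22, adjusted p = 0.285), oligodendrocyte precursors (0.18, adjusted p = 0.124), and pericytes and smooth muscle (0.19, adjusted p = 0.387). Heat shock genes (median 0.23, adjusted p = 0.274), unfolded protein response genes (0.27, adjusted p = 0.333), extracellular matrix genes (0.25, adjusted p = 0.20) and clock genes (0.15, adjusted p = 0.219) were called higher. Interneuron and granule cell genes (-0.14, adjusted p = 0.130) and cholesterol synthesis genes (-0.17, adjusted p = 0.124) were called lower. In the endothelial list Slc2a1 (0.86, SE 0.13, adjusted p = 0.00845) and Vwf (1.71, SE 0.28, adjusted p = 0.0152) rose. In the microglial list Lpl rose (1.83, SE 0.33, adjusted p = 0.0173), as did, in the clock list, Nr1d1 (0.54, SE 0.09, adjusted p = 0.0152). Hspa1b rose (2.19, SE 0.42, adjusted p = 0.0337), and it shares sequence with Hspa1a (1.26, adjusted p = 0.0923), so the division of reads between them is uncertain. With 1 library left out, some preset calls were lost as well, and replicates are of the 2nd set unless given. Without control replicate 2 these were extracellular matrix (adjusted p = 0.175), oligodendrocyte precursors (0.175), interneurons and granule cells (0.116) and pericytes (0.357). Without exposed replicate 3 they were the unfolded protein response (adjusted p = 0.213), precursors (0.140) and pericytes (0.0853). The clock list was lost without control replicate 1 (adjusted p = 0.180), exposed replicate 1 (0.0829) or 2 (0.0873), or exposed replicate 1 of the 1st set (0.0523). Precursors were also lost without control replicate 3 (adjusted p = 0.0522) or exposed replicate 1 (0.0522), and pericytes without control replicate 3 (0.0978) or exposed replicate 2 (0.115).

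Markers of other tissue varied among the high-dose libraries. Hbb-bs, the adult beta globin, stood at 66.0, 127 and 180 CPM in replicates 1, 2 and 3 of the high dose and at 55.7 to 71.4 CPM in their controls. The mean log2 CPM of the neighbouring cortex and striatum list stood 0.78 above the control mean of the set in replicate 3 of the high dose, against 0.14 and -0.12 in replicates 1 and 2, and the list was not called (adjusted p = 0.0989). A separate fit within each set called 4 of the 112 genes (Cxcl10, Acer2, Icam1 and Plin4, of which Acer2 was named after its value was seen). The same setting called 9 genes at the low dose, where the joint fit called 0. Both counts thus depend on fitting the sets together. The DESeq2 Wald test called 291 genes, limma trend on log2(FPKM + 1) 50, and the filter of at least 1 CPM in every library left 69. Without control replicate 3 of the 2nd set 21 genes passed, without exposed replicate 2 of that set 65, and without control replicate 2 of the 1st set, which enters through the shared spread, 70. The balance of direction moved as well, from 91 higher and 21 lower to 80 and 58 without control replicate 2 of the 2nd set, 18 and 3 without its control replicate 3, and 84 and 10 without its exposed replicate 1. With alternatives chosen after the data were seen it was 181 and 118 with the leading residual component as a covariate, and 81 and 51 without the deepest control and exposed library of the 2nd set.

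The aryl hydrocarbon receptor and NRF2 lists were not called at the high dose. The aryl hydrocarbon receptor targets (7 measured) had a median of 0.10 and a mean of -0.25 (adjusted p = 0.381, direction up) with none past the test. Cyp1a1, named after its values were seen, held at most 10 counts in a library and was not among those measured. Cyp1b1 stood at 0.55 (SE 0.19, adjusted p = 0.316) and Nfe2l2 at 0.40 (SE 0.16, adjusted p = 0.376). The NRF2 antioxidant list had a median of 0.05 (adjusted p = 0.253), with Hmox1, heme oxygenase 1, at 0.68 (SE 0.20, adjusted p = 0.190) and Abcc4 at 0.36 (SE 0.12, adjusted p = 0.267). Olfactory sensory neuron genes (median -0.04, mean 0.04, adjusted p = 0.802, direction up), dopaminergic periglomerular genes (median -0.10, adjusted p = 0.293) and homeostatic microglia genes (median 0.14, adjusted p = 0.0900) were not called. Ddc and Th, enzymes of dopamine synthesis, stood at log2 fold changes of 0.38 and -0.24 (adjusted p = 0.502 and 0.531), and Gnal and Gap43 of the sensory neuron list at 0.44 and 0.40, also short of the threshold (adjusted p = 0.404 and 0.584). Olfml3 and Fcrls, markers of resting microglia, stood at 0.51 and 0.68 (adjusted p = 0.12 and 0.123).

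At the low dose no gene passed with edgeR's quasi-likelihood test, whose smallest adjusted p was 0.0737, for Npas4. At an unadjusted p under 0.05 there were 429 genes, 228 higher and 201 lower. Npas4 stood at 78.1 ± 5.85 CPM in the 4 controls (SD) and at 28.9 ± 4.67 CPM in the 3 exposed libraries (log2 fold change -1.43, SE 0.20), with every exposed library below every control. Ier2, a further immediate early gene, stood at -1.17 (SE 0.23, adjusted p = 0.359). Ccl12 stood at 2.73 (SE 0.48, adjusted p = 0.326) and Lrg1 at 2.93 (SE 0.58, adjusted p = 0.359). Rab7 stood at 0.59 (SE 0.12, adjusted p = 0.359), Tomm40l at -0.72 (SE 0.16) and Igdcc4 at -0.49 (SE 0.11), the last 2 with adjusted p = 0.500. The DESeq2 Wald test, which made more false calls than edgeR in the simulation, called 19 genes, with Npas4 and Ccl12 among them. Limma-voom called 2 (Npas4 and Sele), a separate fit of the 1st set called 9 and limma trend on log2(FPKM + 1) called 2. With 1 library left out, 2 genes passed without exposed replicate 2 of the 1st set, without control replicate 1 of the 2nd set and without exposed replicate 1 of the 2nd set, and 1 gene (Npas4) passed without exposed replicate 2 or 3 of the 2nd set.

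In lists, the low dose was called in 15, of which 9 were higher and 6 lower, and 1 call, that of NF-kB feedback and acute phase, held with an estimated correlation (adjusted p = 0.00901) and with fry (adjusted p = 0.0233). That list had a median of 0.63 with 12 of 13 members positive. None passed over all genes and 6 rose when adjusted over the list alone. Sele had no count in the 4 controls and stood at 0.294 ± 0.0347 CPM at the low dose, at least 5.48-fold higher than their floor. The complement list had 13 of 13 positive members and 4 that rose when adjusted over the list alone (median 0.39, adjusted p = 0.0627 with an estimated correlation), with C3 at 2.65 (SE 0.69, adjusted p = 1) and C3ar1 at 0.82 (SE 0.24, adjusted p = 1). Also higher were cytokines and chemokines (median 0.26, adjusted p = 0.0627), neutrophil genes (0.64, adjusted p = 0.0627) and reactive astrocyte genes (0.25, adjusted p = 0.189), each p with an estimated correlation. So were glucocorticoid-responsive genes (0.20, adjusted p = 0.117), antigen presentation (0.21, adjusted p = 0.526), perivascular and peripheral macrophages (0.27, adjusted p = 0.535) and red blood cell genes (0.31, adjusted p = 0.584), each p with an estimated correlation. Called lower were immediate early genes (median -0.52, adjusted p = 0.119), oligodendrocyte and myelin genes (-0.20, 15 of 16 negative, adjusted p = 0.203) and olfactory sensory neuron genes (-0.35, 20 of 20 negative, adjusted p = 0.355), with an estimated correlation. So were tight junction genes (-0.16, adjusted p = 0.189), oligodendrocyte precursors (-0.11, adjusted p = 0.178) and ensheathing glia (-0.20, adjusted p = 0.584), again with an estimated correlation.

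Exposed replicate 1 of the 1st set stood above the other exposed libraries in several of these lists. Its mean log2 CPM, less the control mean of the set, was 0.74 for glucocorticoid-responsive genes, against 0.11 and 0.26 in replicates 2 and 3. It was 0.74 against 0.15 and 0.41 for reactive astrocyte genes, 0.48 against -0.02 and 0.21 for antigen presentation, 1.49 against 0.66 and 0.73 for neutrophil genes, 0.88 against 0.43 and 0.58 for complement, and 1.47 against 0.71 and 1.04 for the NF-kB list. Without it the median of the glucocorticoid list was 0.02 (camera adjusted p = 0.0149) and the antigen presentation call was lost (median 0.06, adjusted p = 0.390), as was that of oligodendrocyte precursors (adjusted p = 0.197). The NF-kB list without it had a median of 0.56 and its call with an estimated correlation was kept (adjusted p = 0.00102), as it was without each other library. Further calls were lost without 1 library of the 1st set. Without control replicate 1 these were ensheathing glia (adjusted p = 0.175), precursors (0.119) and red blood cells, and without control replicate 2 precursors (0.0733) and red blood cells (0.213). Without control replicate 4 they were ensheathing glia (adjusted p = 0.0546) and perivascular macrophages (0.0619), without exposed replicate 2 precursors (0.124) and tight junctions (0.114), and without exposed replicate 3 ensheathing glia (0.159) and perivascular macrophages.

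None of the leading members of those lists passed. Lcn2, a secreted iron-binding protein of innate defence, stands on the NF-kB, reactive astrocyte and neutrophil lists. It varied from library to library at 5.59 ± 7.09 CPM, against 0.375 ± 0.470 CPM in the controls (log2 fold change 3.87, SE 1.11). Il1b stood at 2.40 (SE 0.77), Osmr at 0.78 (SE 0.19), Plin4 at 2.09 (SE 0.44), Hif3a at 0.94 (SE 0.22), H2-Ab1 at 0.76 (SE 0.28) and F13a1 at 0.77 (SE 0.27). In the lists called lower, Ugt8a and Mobp of the myelin list stood at -0.47 (SE 0.17) and -0.22 (SE 0.10), Gpr17 and Bcas1 of the precursor list at -0.48 (SE 0.16) and -0.27 (SE 0.10), and Adcy3 and Ebf2 of the sensory neuron list at -0.18 (SE 0.09) and -0.78 (SE 0.40). The mucosal gene Cyp2a5 stood at 23.3 CPM in control replicate 1 of the 1st set, against 0.0694 to 4.01 CPM in the other libraries of that set, beside the lower values of the sensory neuron list. The aryl hydrocarbon receptor list (median -0.02, adjusted p = 0.862), the NRF2 list (0.01, adjusted p = 0.138), dopaminergic periglomerular genes (0.03, adjusted p = 0.999) and homeostatic microglia (median 0.02, mean -0.01, adjusted p = 0.920, direction down) were not called. Hmox1 stood at 0.37 (SE 0.20, adjusted p = 1) and Th at 0.15 (SE 0.11, adjusted p = 1).

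**Figure D2:**
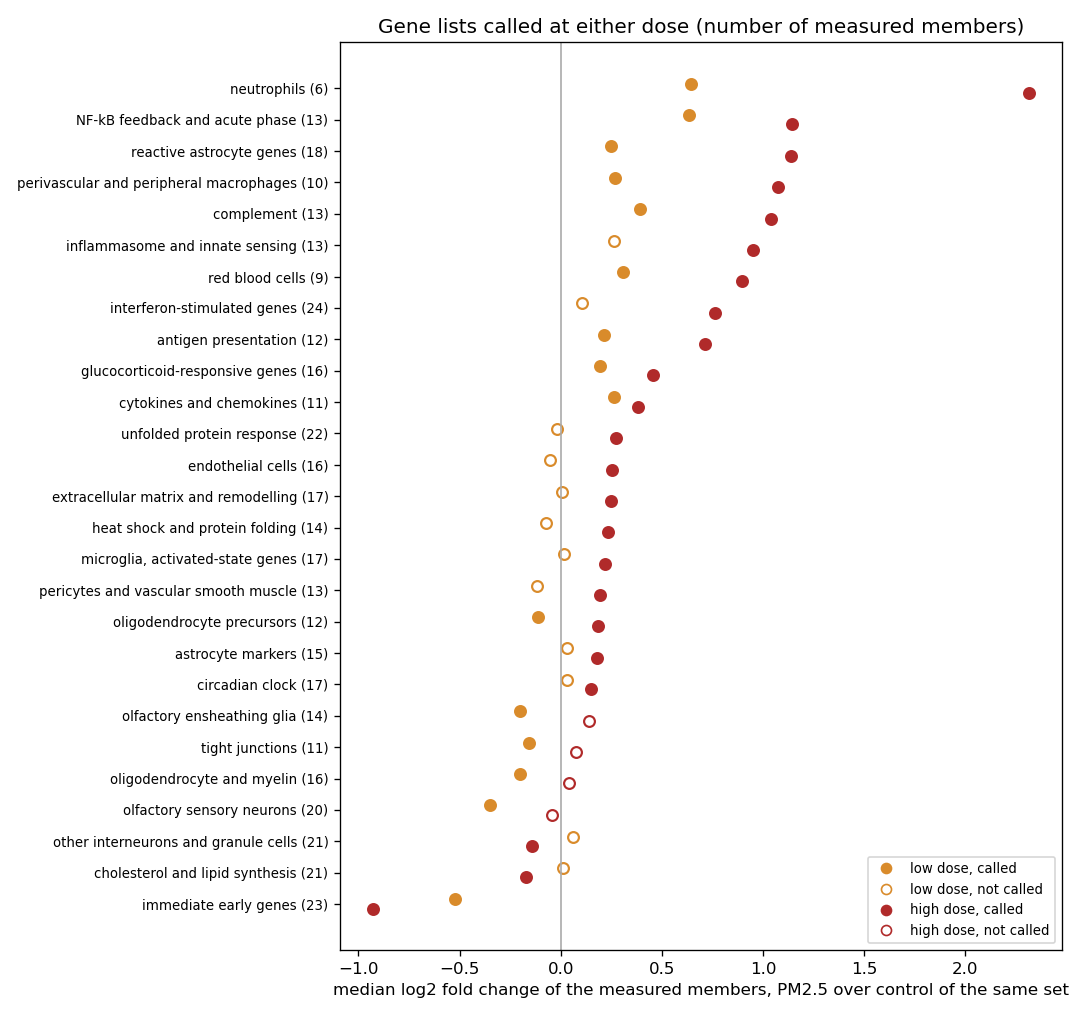
Median log2 fold change of the measured members of each gene list called at either dose, against controls of the same set, for the low dose and the high dose; filled points were called by camera with the preset correlation and open points were not, and numbers are measured members. Immediate early genes had medians of -0.52 and -0.93 at the low and high dose, and the NF-kB list 0.63 and 1.14.

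The difference between the high-dose and low-dose responses was tested directly. Icam1 was the 1 gene that passed, with log2 fold changes of 0.63 (SE 0.18) at the low dose and 2.71 (SE 0.21) at the high dose and a difference of 2.08 (SE 0.28, adjusted p = 0.0433). At an unadjusted p under 0.05 there were 1046 genes. The DESeq2 Wald test called 17, and limma-voom called 0. By camera 30 lists differed, 27 more positive and 3 more negative at the high dose, and none did with an estimated correlation or with fry. With 1 library left out, Icam1 passed only without control replicate 1 of the 2nd set, where 6 genes passed, and without exposed replicate 1 of that set, where 2 passed. No gene passed without any 1 of control replicates 1, 2, 3 and 4 or exposed replicates 1 and 3 of the 1st set, or without control replicate 3 or exposed replicate 3 of the 2nd set. Without exposed replicate 2 of the 1st set, control replicate 2 or exposed replicate 2 of the 2nd set, 1 gene other than Icam1 passed (Eif4e, Gm37342 and Hspa1b, named after their values were seen). Dose and set cannot be told apart in this contrast.

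The mean response over the doses gave 86 genes, 74 higher and 12 lower, with 1126 genes at an unadjusted p under 0.05. The largest rises were in Lcn2 (mean log2 fold change 4.79, adjusted p = 0.0362), Ccl12 (4.03, adjusted p = 0.000114), Lrg1 (3.37, adjusted p = 0.00189) and Msr1 (3.23, adjusted p = 0.0388). The largest falls were in Npas4 (-1.64, adjusted p = 0.000114), Fos (-1.58, adjusted p = 0.0287), Ier2 (-1.16, adjusted p = 0.00404) and Btg2 (-1.06, adjusted p = 0.00877), all genes induced by activity or stimulation. Each of these 8 had the same sign at both doses. List tests of the mean response were added after the data were seen. By camera 23 lists were called, 19 higher and 4 lower, of which 10 held with an estimated correlation, and fry called these and interferon-stimulated genes (adjusted p = 0.0420). Of the 23 immediate early genes 4 fell (Npas4, Fos, Ier2 and Btg2) and 1 rose (Ier3), with a median of -0.71 (adjusted p = 0.0392 with an estimated correlation and 0.0407 with fry). The call with an estimated correlation was lost without control replicate 2 of the 1st set (adjusted p = 0.0715) or its exposed replicate 2 (0.0934) or 3 (0.0725). It was also lost without control replicate 2 (adjusted p = 0.149) or 3 (0.0868) or exposed replicate 1 (0.0788) or 2 (0.0628) of the 2nd set. The other 9 were higher, and 6 of them kept the call without any 1 library: NF-kB (adjusted p = 0.000206 with an estimated correlation), neutrophils (0.00136), complement (0.00223), reactive astrocyte genes (0.00244), cytokines (0.00627) and glucocorticoid-responsive genes (0.00627). Those that lost it without some libraries were the inflammasome list (adjusted p = 0.0169, highest 0.0520), antigen presentation (0.0307, highest 0.0783) and perivascular macrophages (0.0392, highest 0.113). The count was 36 without exposed replicate 1 of the 1st set, 43 without exposed replicate 3 of that set, 49, 53 and 49 without its control replicates 1, 3 and 4, and 49 without control replicate 3 of the 2nd set. Across the 17467 genes, the log2 fold changes of the doses, which share no library, had a Pearson correlation of 0.217 (jackknife SE 0.104), against a median of -0.00114 and a highest of 0.228 in 99 regroupings of the libraries within the sets. Genes are not independent replicates. The correlation was 0.0644 with no filter on low counts, 0.104 with at least 1 CPM in every library and 0.118 on log2(FPKM + 1).

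**Figure D3:**
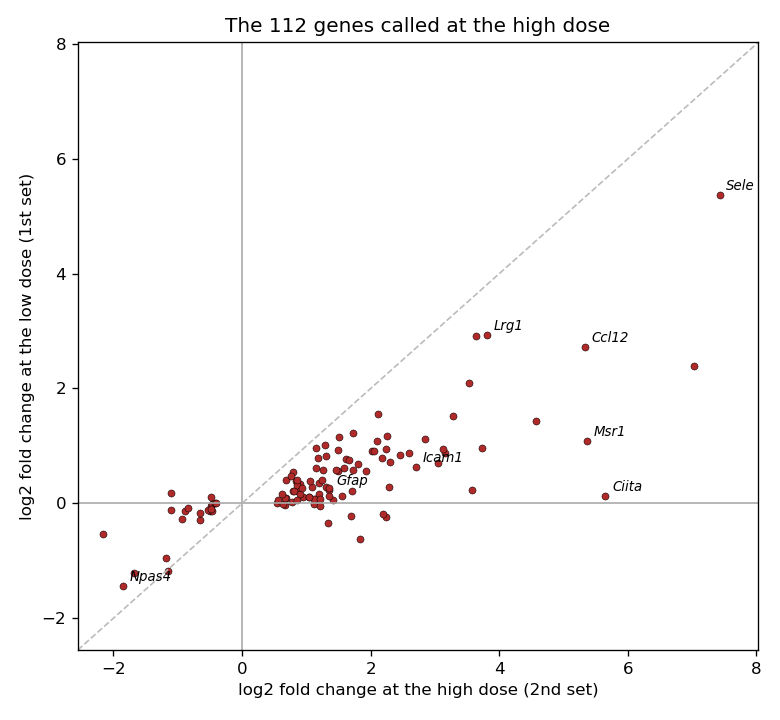
Log2 fold change at the low dose (1st set) against that at the high dose (2nd set) for the 112 genes called at the high dose, 1 point per gene, with a dashed line of equal change. Of these genes 99 had the same sign at both doses, and Ccl12 stood at 5.33 at the high and 2.73 at the low dose.

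The control groups were compared to measure the distance between the sets. Between them 3364 genes differed, 1837 higher and 1527 lower in the 2nd set. With upper-quartile factors 1307 were higher and 1931 lower of 3238. With no filter on low counts 2293 were higher and 1150 lower, and at a fold of at least 1.5 459 and 1024. The balance of direction thus depended on the scaling, the filter and the fold threshold. Of the differing genes 129 lay on X or Y, which is 3.83% of them against 3.28% of the genes tested. Without control replicate 1 or 2 of the 1st set 2069 and 2142 genes differed, and without control replicate 2 of the 2nd set 1340.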

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

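All tests of explanations in this part were chosen after the result was seen, except those of short-lived transcripts and of gene length and the splits of the libraries, which were written before. The splits for lists of the mean response were also chosen after.

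Single control libraries of the 1st set stood apart from the other 3. The gap to the nearest control passed Dixon's 95% limit in 11 of 148 tests, where chance gives about 7.4. In replicate 4 these were Mobp at 256 CPM, Cgn at 3.47 CPM, Slc4a1 at 0.992 CPM and the oligodendrocyte and myelin list at a mean log2 CPM of 5.35. In replicate 1 these were F13a1 at 4.31, Ccr2 at 1.74, Matn2 at 47.5, Cyp1a2 at 3.10 and Pycard at 3.17 CPM. In replicate 3 the pericyte and smooth muscle list stood at a mean log2 CPM of 3.55 and the neutrophil list at -0.44.

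The responses at the doses differed by test in Icam1, by 2.08, and in 30 lists by camera with the preset correlation, none of them with an estimated correlation (smallest adjusted p 0.0570) or fry (0.0505). The median differences, high minus low, of lists of inflammation and glia were 0.85 for reactive astrocyte genes, 0.69 for interferon-stimulated genes, 0.45 for complement, 0.68 for NF-kB feedback, 0.74 for inflammasome genes, 0.36 for antigen presentation, 0.34 for cytokines, 0.74 for perivascular macrophages, 1.53 for neutrophils, 0.19 for activated microglia and 0.19 for astrocyte markers. Those of stress, metabolism and matrix lists were 0.24 for heat shock, 0.19 for the unfolded protein response, 0.27 for glucocorticoid-responsive genes, 0.22 for p53 targets, 0.33 for extracellular matrix, -0.13 for cholesterol synthesis and -0.15 for oxidative phosphorylation. Those of cell type lists were 0.25 for oligodendrocyte precursors, 0.22 for myelin, 0.31 for olfactory sensory neurons, 1.3 for olfactory mucosa, 0.30 for ensheathing glia, 0.25 for pericytes, 0.20 for endothelium, 0.35 for tight junctions, 0.39 for choroid plexus, 0.18 for cortex and striatum, 0.32 for red blood cells and -0.18 for interneurons and granule cells. In 27 of 100 regroupings of the libraries within the sets, the real one included, at least 1 gene differed (real 1, highest other 37), so chance is not excluded for the gene count. For the number of lists with the preset correlation it was 2 of 100 (real 30, highest other 30), a share under 0.05. As 1 other regrouping equalled the real count, chance is made less likely but is not excluded. No single list was called with an estimated correlation or fry. Dose, set and the sex of the libraries are confounded in these differences.

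The first pattern weighed is the 91 genes that rose at the high dose. After thinning every library to the lowest total 74 of them still rose, and 67 did without exposed replicate 3, the library with the highest score of the cortex and striatum list, which argues against depth and against tissue of that 1 library as the whole cause. Neutrophils could not be excluded: 45 of the 91 gained more CPM than S100a8 and S100a9 together (gain 4.93 CPM), just short of the bound set, so an entry of blood cells may account for part. Of the 10 splits of the 6 libraries 2 gave as many genes (real 112, highest other 688) and 2 as many lists (real 23, highest other 26), and 10 splits are too few for a share under 0.05. The split with 688 genes set control replicate 2 and exposed replicates 2 and 3 against the rest, several times the real count, which points to a structure of these samples beside the exposure. Malat1, an abundant nuclear RNA, made up 0.955, 1.40 and 1.15% of their counts, against 1.55, 1.83 and 1.64% in control replicates 1 and 3 and exposed replicate 1, so RNA composition may be part of it, which was not tested.

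The second pattern is the immediate early genes, with a median mean response of -0.71. The list was called with an estimated correlation in the mean response (adjusted p = 0.0392) but at neither dose alone. Other short-lived transcripts had a median of -0.000674 (24 genes, from -0.45 in Gadd45a to 1.03 in Cebpd) and the synapse list one of -0.00441. The SD over genes divided by the square root of their number was 0.0576 and 0.0130. That value treats genes as replicates, so it does not measure the spread of samples. The medians argue against a general loss of short-lived transcripts, while a loss limited to some transcripts stays open. For synapse genes they argue against fewer neurons as the whole cause. The interneuron and granule cell list had a median mean response of -0.04. At the high dose its median was -0.14, with 18 of 21 members negative, so a smaller loss of these cells stays open. A different time of day may contribute and cannot be told apart: 10 strongly cycling clock genes had a median absolute change of 0.223 at the high and 0.139 at the low dose, and 0 had an unadjusted p under 0.05 in both sets. The exposure stays open as a biological explanation, as does handling before collection, which was not tested. For the 86 genes of the mean response 1 of 100 regroupings, the real one, gave as many (highest other 4). This share under 0.05 makes chance unlikely but does not exclude it, and 5 genes passed with the replicate block. For the lists of the mean response 12 of 100 gave as many with the preset correlation (real 23, highest other 28), so chance is not excluded. With an estimated one it was 1 of 100 (real 10, highest other 9), which makes chance less likely by a narrow margin.

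The third pattern is the 3364 genes that differed between the control groups. Of them, 3.83% lay on X or Y. As only 3.28% of the 17467 genes tested lie there, X and Y genes could not have formed the bulk. This share thus says nothing on sex as a cause. Of the 3364 genes, 3057 still differed after thinning to the lowest total, which argues against depth. Gene length could contribute: Spearman's rho of the change with length, inferred from the FPKM, was -0.147 across genes, between the bounds set. Of 35 splits 1, the real one, gave as many genes (highest other 1). Every other split mixed libraries of the sets, which Xist and Y genes already part, so this shows only that the sets differ. Sex, which expression of Xist and Y genes places apart in the sets against the male label, can act beyond X and Y and stays untested, since it is confounded with set.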

How the results depend on the processing

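The residual component, the thinned libraries, the estimated correlation with 1 library left out, the lists of the mean response, the removal of gene groups and of the deepest libraries, and every value of the low-dose change of the high-dose genes were chosen after the data were seen. Of 1954 values of named genes, 1718 kept direction and side of the threshold, 191 lost the call, 45 gained one and 0 turned direction. They cover only DESeq2 size factors, the DESeq2 Wald test, the replicate block, the separate fit and left-out libraries (1505 values). Values that never passed count as kept. The fold change at a dose barely depends on libraries of the other set, so many values could hardly turn direction. Of 34 named genes called at the high dose, 29 lost the call with the replicate block, 30 in the separate fit and 22 without control replicate 3 of the 2nd set. Causes were not tested. Separate fits and left-out libraries use fewer samples, and the stricter filters fewer genes. Fewer samples alone do not explain the separate fit, which raised low-dose calls from 0 to 9 and cut high-dose calls from 112 to 4. Replicates lay further apart in the 2nd set, with log CPM correlations of 0.970 to 0.985 against 0.983 to 0.986 in the 1st. The joint fit shares 1 spread over both sets, so the counts of 0 and 112 do not compare the doses alone.

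Genes at the low dose (0) became 19 with the DESeq2 Wald test, 2 with limma-voom, 2 with limma trend on FPKM, 9 in the separate fit, 2 with pooled controls, 1 with the residual component and 1 without the deepest libraries (0 to 2 with 1 library left out). Genes at the high dose (112) became 69 with at least 1 CPM in every library, 5 with the replicate block, 291 with DESeq2, 50 with FPKM, 4 in the separate fit and 299 with the residual component (21 to 138 with 1 library left out). Genes that differed between the doses (1) became 2 with no filter, 0 with the block, 17 with DESeq2, 0 with voom, 0 with FPKM, 0 with pooled controls and 3 with the residual component (0 to 6). The mean response (86) became 44 with the strict filter, 5 with the block, 195 with DESeq2, 36 with FPKM, 41 with pooled controls and 151 with the residual component (36 to 93). The control difference (3364) became 983 with the block, 1483 at a fold of at least 1.5 and 5914 with the residual component (1340 to 4073).

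Lists at the low dose (15) became 1 with an estimated correlation and 1 with fry (13 to 18), at the high dose (23) 8 and 14 (23 to 26), and for the difference (30) 0 and 0, and 19 without the deepest libraries (21 to 31). Lists of the mean response (23) became 10 and 11 (20 to 24). The correlation (0.217) became 0.0644 with no filter, 0.104 with the strict filter and 0.118 with FPKM (0.173 to 0.278). The low-dose change of the high-dose genes (0.573) became 0.344 with the strict filter, 0.264 with FPKM and 0.796 with pooled controls (0.494 to 0.644).

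The labels do not say whether the numbers pair the samples. Correlations of libraries were taken after the group means were removed. For the same number they ran from 0.00424 to 0.0583 in the 1st set and from -0.341 to 0.134 in the 2nd. For different numbers they reached 0.0578 and 0.455. No pairing showed, but deviations within groups of 3 or 4 are tied to each other, so pairing is not excluded. With the replicate block the low dose gave 0 genes, the high dose 5 and the mean response 5, and the correlation of the doses was 0.177. Lists could not be run without mitochondrial genes, which empties 1 list. Separate fits give no difference, mean or control contrast, and pooled controls no control contrast or correlation. Limma trend on log2(FPKM + 1) was not repeated with another pseudocount or with no filter, since the main tests used the counts.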

Other observations

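The test of the high-dose genes in the 1st set was chosen after the result was seen, as were the regroupings under other filters, while the other splits of the libraries were written before.

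The control groups also differed in lists, with 17 called with the preset correlation, none with an estimated one and 19 with fry. Of 29 nuclear-encoded oxidative phosphorylation genes 22 were higher in the 2nd set and none lower (median 0.62, adjusted p = 0.512 with an estimated correlation and 0.0274 with fry), and of 33 cytosolic ribosomal protein genes 21 were higher (median 0.55, adjusted p = 0.512 and 0.0305). Of 15 meningeal and perivascular fibroblast genes 9 were lower (median -0.93, adjusted p = 0.512 and 0.0146), as were 9 of 13 pericyte and smooth muscle genes (median -0.76, adjusted p = 0.511 and 0.00337) and 10 of 17 extracellular matrix genes (median -0.51, adjusted p = 0.279 and 0.000785). Upper-quartile factors moved the median of all genes by -0.06 in this contrast. Malat1, chosen after its values were seen, made up 1.90 to 2.11% of counts in the controls of the 1st set and 0.955 to 1.83% in those of the 2nd, and did not pass (log2 fold change -0.43, adjusted p = 0.0804). A difference in RNA composition between the sets was not tested and stays open.

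A hypothesis is that the low dose moved the genes called at the high dose the same way, too weakly to pass alone. Of the 112 genes 99 had the same sign at the low dose, 82 of 91 that rose and 17 of 21 that fell, and 41 had an unadjusted p under 0.05 there. Their mean change, signed by the high-dose direction, was 0.57 at the low dose and 1.70 at the high dose. Over the 35 splits of the 7 libraries of the 1st set the real one gave the highest mean of log CPM differences, 0.492 against 0.322. The two-sided permutation p was 0.0286, the smallest these splits can give. The 112 genes came from the joint fit, whose spread uses the real groups of the 1st set. The real split may thus be favoured, and the p is not exact. The values are consistent with a shared response, found and tested on the same data. For the low-dose count the real value is 0, so that all 35 of 35 splits give as many (highest other 3), which says nothing on chance. For the low-dose lists 3 of 35 splits gave as many (real 15, highest other 16), so chance is not excluded. For the correlation of 0.217 across genes, 2 of 100 regroupings were as large with the default filter (highest other 0.228). With no filter it was 1 of 100 (real 0.0644, highest other 0.0593). These shares under 0.05 make chance less likely but do not exclude it. With at least 1 CPM in every library 16 of 100 were as large (real 0.104, highest other 0.181), and on log2(FPKM + 1) 13 of 100 (real 0.118, highest other 0.192). Chance is thus not excluded for the correlation, and regroupings matched it most often among genes of higher expression.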
